A study of Rattus norvegicus with 68 samples.

How the data were processed

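Gene expression was measured on 68 single-colour Affymetrix Rat230_2 arrays, each hybridised with RNA from the nasal epithelial cells of 1 male F344 rat. Per the labels, rats of 8 weeks breathed formaldehyde in whole-body chambers for 6 h per day on 5 days per week. Proteases released the cells from level II nasal tissue, from which the maxilloturbinate and the olfactory lining had been discarded. The arrays formed 17 groups of 4 animals by dose and time, and animals were treated as independent replicates, since no label pairs them. The series text gives a time of 1 week, which was treated here as the 5 d of the labels. The titles of all exposed samples carry HCHO, the formula of formaldehyde. Those of 0 ppm carry codes that begin with ACO and differ between 5 d and 13 w, with no meaning given. The labels state no batch or chamber behind these codes. If there was any, it could not be separated from dose, or at 0 ppm from time, and the 4 w comparisons use no 0 ppm array. For 19 of the 20 samples of 4 w the treatment field gives a duration of 5 days while the title, description and time tag give 4 weeks, and the latter were followed. No 0 ppm arrays of 4 w were analysed here, so the 0.7 ppm group, which was itself exposed, was the reference at that time.

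The deposited values are log2 signals that the authors computed with RMA (no version given) from GCOS 1.0 output, per the submitters' processing notes. They were used as deposited, without further scaling. The values of 31099 probe sets ran from 3.17 to 15.4, array medians from 6.82 to 6.96, and 0 values were missing. Of the probe sets, 20832 named 1 gene, 436 named several and 9831 named none. For each of 14217 genes the probe set with the highest mean over all arrays stood for the gene, chosen among 2 or more for 4525 genes. Probe sets without a gene name or with several were left out because their results could not be assigned to a gene, and the 57 array control probe sets because they do not stand for genes.

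Limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all arrays (lmFit), with moderated tests (eBayes) on 51 residual degrees of freedom plus 2.85 from the prior. Each dose was compared with its reference at the same time. The difference between 2 such responses was tested as an interaction contrast for 13 w against 5 d at 6, 10 and 15 ppm, and with 0.7 ppm as reference for 4 w against 5 d and 13 w against 4 w at 15 ppm. The 0 ppm groups of 13 w and 5 d were compared as well. P values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. The 4 animals per group limit the precision, and the median SE of a change was 0.104 on the log2 scale.

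A total of 27 gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists within a contrast. Members past the threshold were counted over all genes and also with adjustment over the list alone. Sets of genes called at 15 ppm were tested with fry at the lower doses of another time. The overlap of calls between doses that shared a reference was set beside fits with split references, and the covariance of their changes beside simulated unchanged groups. The contrasts, tests, gene lists, thresholds and rule for naming genes were fixed before the data were examined. By that rule the text may name, among called genes whose groups did not overlap, those with the largest changes (10 in each direction at 15 ppm and 5 at other doses). It may also name up to 4 called members of each list by smallest adjusted p, the 5 largest differences of each sign in each interaction and in the 0 ppm comparison, and 10 single genes fixed in advance. It names part of these, and genes named outside the rule are said to be so.

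The fit was tested on simulated data with the spread of the real arrays and 50 changed genes of each size. For 15 ppm against 0 ppm at 5 d it called 38 (76%) of the genes changed by 0.5 on the log2 scale, 48 (96%) at 1, 50 (100%) at 2 and 45 (90%) at -1, and 8 of 189 calls (4.23%) were of unchanged genes. For the interaction of 13 w and 5 d at 15 ppm it called 24 (48%), 46 (92%), 50 (100%) and 42 (84%), with 8 unchanged genes among 170 calls (4.71%). A list of 36 genes shifted by 0.5 had a camera adjusted p = 7.8e-56, and 0 of 20 lists that were not shifted were called. The simulated genes were drawn independently of each other, and 189 were called at 15 ppm after 5 d, against 5364 on the real arrays. The shares of recovered and of false calls therefore need not hold on the real arrays. Because of that independence, the list test could not show how camera behaves when the genes of a list are correlated.

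Alternatives tried were centring each array on its median, cyclic loess, and keeping only genes with a highest group mean of at least 6. The mean of all probe sets of a gene, every probe set by itself and a change of at least 1.5-fold were also tried. So were adjustment over all contrasts, array weights, a trended and robust prior, and fits of the contrast's own time points. Covariates were the RNA integrity number and the difference between the 3' and 5' control probe sets of beta-actin. Other references were 0.7 ppm at 5 d and 13 w and the mean of the 0 ppm groups at 4 w. Arrays were left out 1 at a time, and the array with an RNA integrity number of 5.4 was left out by itself. Lists were also tested with camera at an estimated correlation and with fry, and the projected sets with camera. Covariates from the mean of the olfactory list, without or with that of the fibroblast list, were added after the data had been seen, as was a fit without the 5 arrays that lack an RNA integrity number, which the covariate of that number also leaves out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.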

Results

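Whole-transcriptome array signals were measured in nasal epithelial cells of male F344 rats that breathed formaldehyde at 0, 0.7, 2, 6, 10 or 15 ppm. The 68 arrays, each from 1 animal, fell into 17 groups of 4 animals defined by dose and by exposure time, which was 5 d, 4 w or 13 w. Every dose was present at 5 d and 13 w, and the 4 w arrays used here ran from 0.7 to 15 ppm, so that 0.7 ppm served as the reference at 4 w. Array medians lay between 6.82 and 6.96 on the log2 scale, and arrays of 1 group correlated across probe sets at 0.977 to 0.996. The titles of the exposed arrays carry HCHO, the formula of formaldehyde. Those of the 0 ppm arrays carry codes that begin with ACO, whose meaning the labels do not give and which cannot be separated from dose. The comparisons asked at which concentration and after how long inhaled formaldehyde altered gene expression in the lining of the nose. Changes are given as log2 differences ± SE from the limma fit, with n = 4 animals in each group, and adjusted p as Benjamini-Hochberg values over 14217 genes. The SE rests on 1 spread per gene pooled over all 17 groups, so it does not show the spread of the groups compared. A mean under 6 was treated as low signal. For genes with such a reference, among them Areg, Cdkn2a, Cxcl11, Ccl7, Mmp3 and Fst, no fold is given, and the size and order of their fitted log2 changes are uncertain beyond the printed SE. The genes with the largest changes named at each dose were called genes whose 4 exposed arrays all lay beyond all 4 reference arrays, an arrangement that chance gives for 2.86% of genes.

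The number of genes called rose with dose at each time. After 5 d, limma called 0, 4, 1256, 2209 and 5364 genes against 0 ppm, in order of dose from 0.7 to 15 ppm. After 13 w the counts in the same order were 0, 1, 1737, 3750 and 6278. At 4 w, 2, 6, 10 and 15 ppm differed from 0.7 ppm in 3, 467, 2102 and 5318 genes. At 0.7 ppm, where limma called 0 genes at both times, 1110 genes at 5 d (7.81%) and 626 at 13 w (4.40%) had an unadjusted p under 0.05. Chance alone gives a share of about 0.05. Some other settings, given in the section on processing, called genes at 0.7 ppm. The count of called genes at 5 d was 5 without 0 ppm animal 210 and 1 without 0.7 ppm animal 235, and that at 13 w was 1 without 0.7 ppm animal 259. The RNA integrity number was 8.47 ± 0.21 (SD, n = 3 with a value), 8.50 ± 0.36 (n = 3) and 8.33 ± 0.33 (n = 4) at 6, 10 and 15 ppm after 5 d, against 7.68 ± 0.29 (n = 4) at 0 ppm. After 13 w it was 8.43 ± 0.15 (n = 4), 8.45 ± 0.10 (n = 4) and 8.90 ± 0.36 (n = 3), against 7.57 ± 0.23 (n = 3). With that number as a covariate, which also leaves out the arrays without a value, the counts at 6, 10 and 15 ppm were 896, 1911 and 5003 after 5 d and 1438, 3009 and 4786 after 13 w. Leaving out those arrays without the covariate gave 1051, 2355 and 5339 after 5 d and 1477, 3303 and 5522 after 13 w.

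**Figure D1:**
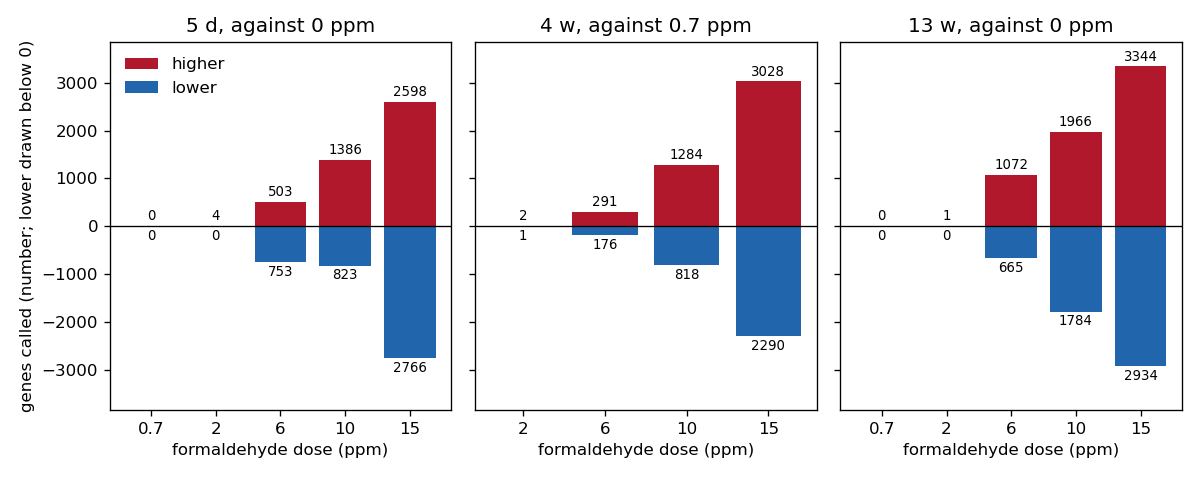
Number of genes called higher (bars upward) and lower (bars downward) than the reference by limma at an adjusted p under 0.05, by formaldehyde dose in ppm, in 1 panel per exposure time. The reference was 0 ppm at 5 d and 13 w and 0.7 ppm at 4 w, and the counts at 15 ppm were 2598 higher and 2766 lower at 5 d and 3344 and 2934 at 13 w.

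After 5 d at 2 ppm, 4 genes were higher than at 0 ppm. Srxn1, which encodes sulfiredoxin, rose by 1.18 ± 0.18 (adjusted p = 2.6e-04), a 2.26-fold increase. Hmox1, the inducible enzyme of heme breakdown, rose by 1.28 ± 0.22 (adjusted p = 0.00333), and Slc7a11, a subunit of the cystine importer, by 1.25 ± 0.25 (adjusted p = 0.0236). Maff, a small Maf transcription factor, rose by 1.04 ± 0.20 (adjusted p = 0.0138). The first 3 belonged to the list of Nrf2 targets and glutathione genes, in which 3 of 36 members rose and 0 fell (9 and 0 adjusted over the list alone). For Nrf2 and glutathione genes, camera gave adjusted p = 7.7e-13, and adjusted p = 0.201 with an estimated correlation. Mitosis genes had a median change of 0.23 with 0 of 51 called (0 higher and 0 lower when adjusted over the list alone). Tested as a list, mitosis genes had a camera adjusted p = 8.3e-14 (adjusted p = 0.424 with an estimated correlation). Ciliated cell genes had a median of -0.30 with 0 of 52 called (0 higher and 0 lower when adjusted over the list alone). Ciliated cell genes had a camera adjusted p = 1.6e-16, and adjusted p = 0.424 with an estimated correlation. The formaldehyde-oxidising enzymes Adh5 and Aldh2 had changes of -0.10 and 0.03, neither of which passed (adjusted p = 0.955 and 0.979). The count of 4 went to 0 with 0.7 ppm as the reference or with the 5 d arrays fitted alone, and to 36 with array weights. With adjustment over all contrasts together, which shares its threshold with the high doses, it went to 118. It was 2 without 0 ppm animal 210 or without 2 ppm animals 265 or 266, and 1 without 2 ppm animal 268.

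After 5 d at 6 ppm, 503 genes were higher and 753 lower than at 0 ppm, 226 of them by at least 1.5-fold. Sprr1b, a precursor protein of the cornified envelope, rose by 3.98 ± 0.40 (adjusted p = 7.4e-10), and Areg, the epidermal growth factor receptor ligand amphiregulin, by 2.89 ± 0.32 (adjusted p = 1.2e-08). Serpinb2, an inhibitor of plasminogen activators, rose by 2.04 ± 0.44 and the keratin gene Krt12 by 2.00 ± 0.42. The B cell chemokine gene Cxcl13 fell by 2.53 ± 0.46 (adjusted p = 2.7e-04), and the urotensin receptor gene Uts2r by 1.74 ± 0.31. In the mitosis list 31 of 51 members rose and 0 fell (39 and 0 adjusted over the list alone), and in the list of S phase and replication genes 12 of 37 members rose and 0 fell (21 and 0 adjusted over the list alone). For mitosis and S phase genes, camera gave adjusted p = 1.2e-22 and 1.6e-12, and adjusted p = 0.165 and 0.165 with an estimated correlation. In the ribosome biogenesis list 13 of 32 members rose and 0 fell (22 and 0 adjusted over the list alone), with Nop58 at 0.58 ± 0.09. Tested as a list, ribosome biogenesis genes had a camera adjusted p = 1.8e-15 (adjusted p = 0.165 with an estimated correlation). In the squamous differentiation list 9 of 37 members rose and 0 fell (21 and 0 adjusted over the list alone). Squamous differentiation genes had a camera adjusted p = 4.9e-14, and adjusted p = 0.18 with an estimated correlation. In the list of growth factor receptor ligands and immediate early genes 8 of 31 members rose and 0 fell (9 and 0 adjusted over the list alone). For growth factor and immediate early genes, camera gave adjusted p = 2.0e-06, and adjusted p = 0.165 with an estimated correlation. Among Nrf2 and glutathione genes 11 of 36 members rose and 2 fell (11 and 4 adjusted over the list alone). Tested as a list, Nrf2 and glutathione genes had a camera adjusted p = 2.3e-05 (adjusted p = 0.285 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose by 1.08 ± 0.14, and Aldh2, the mitochondrial aldehyde dehydrogenase, fell by 0.52 ± 0.12. In the macrophage and dendritic cell list 0 of 27 members rose and 5 fell (0 and 9 adjusted over the list alone). Macrophage and dendritic cell genes had a camera adjusted p = 9.7e-06, and adjusted p = 0.37 with an estimated correlation. In the fibroblast, cartilage and bone list 0 of 37 members rose and 3 fell (0 and 3 adjusted over the list alone), including Spp1 at -1.47 ± 0.42 and Ogn at -1.48 ± 0.48. For fibroblast genes, camera gave adjusted p = 9.5e-06, and adjusted p = 0.523 with an estimated correlation. On the same arrays the difference between the 3' and 5' control probe sets of beta-actin was 2.61 ± 0.17 (SD, n = 4) against 1.71 ± 0.20 at 0 ppm, and the count went to 595 (425 higher, 170 lower) with that difference as a covariate. The share of called genes that was higher, 40.0%, became 61.6% with each array centred on its median and 51.8% with cyclic loess, and the count was 2606 with array weights, 818 without 0 ppm animal 204, 815 without 0 ppm animal 207 and 558 without 6 ppm animal 300.

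At 10 ppm after 5 d, 1386 genes were higher and 823 lower, 468 of them by at least 1.5-fold. Sprr1b rose by 4.44 ± 0.40 (adjusted p = 6.4e-12), Areg by 3.70 ± 0.32 (adjusted p = 2.3e-12) and Plaur, the urokinase receptor gene, by 2.36 ± 0.27. Slc7a11 rose by 2.57 ± 0.25, while Cxcl13 fell by 2.19 ± 0.46 and Uts2r by 1.20 ± 0.31. Cell division genes stood out as a group: in the mitosis list 46 of 51 members rose and 1 fell (46 and 1 adjusted over the list alone), with the cyclin-dependent kinase Cdk1 at 1.18 ± 0.13 and cyclin Ccnb2 at 1.37 ± 0.16. Tested as a list, mitosis genes had a camera adjusted p = 6.2e-56 (adjusted p = 0.00569 with an estimated correlation). In the S phase and replication list 32 of 37 members rose and 0 fell (34 and 0 adjusted over the list alone), with Pcna at 0.62 ± 0.07 and Uhrf1 at 1.75 ± 0.21. S phase genes had a camera adjusted p = 1.6e-30, and adjusted p = 0.00764 with an estimated correlation. In the list of DNA crosslink and other DNA repair genes 11 of 39 members rose and 2 fell (12 and 3 adjusted over the list alone), with the checkpoint kinase gene Chek1 at 1.17 ± 0.15 and the Fanconi anaemia gene Fancd2 at 0.67 ± 0.12. For DNA repair genes, camera gave adjusted p = 4.4e-04, and adjusted p = 0.232 with an estimated correlation. Of the p53 targets 8 of 24 members rose and 0 fell (10 and 2 adjusted over the list alone), led by Cdkn1a at 1.29 ± 0.14 and Ccng1 at 0.79 ± 0.10. Tested as a list, p53 target genes had a camera adjusted p = 4.4e-04 (adjusted p = 0.103 with an estimated correlation). Among heat shock genes and metallothioneins 8 of 22 members rose and 0 fell (9 and 0 adjusted over the list alone), with the mitochondrial chaperonin Hspd1 at 0.42 ± 0.07. Heat shock genes had a camera adjusted p = 0.00102, and adjusted p = 0.232 with an estimated correlation. Of the epithelial P450 and other xenobiotic metabolism genes 0 of 37 members rose and 10 fell (1 and 12 adjusted over the list alone), with Cyp4b1 at -0.93 ± 0.17 and the carboxylesterase Ces1d at -0.70 ± 0.12. For P450 and xenobiotic genes, camera gave adjusted p = 3.4e-05, and adjusted p = 0.0512 with an estimated correlation. The count was 1362 without 10 ppm animal 329.

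At 15 ppm after 5 d, 2598 genes were higher and 2766 lower than at 0 ppm, 1740 of them by at least 1.5-fold. Cxcl11 rose by 6.12 ± 0.51 (adjusted p = 1.7e-14) and Cxcl10 by 5.01 ± 0.54; both encode interferon-induced ligands of the receptor on activated T cells. The monocyte chemokine genes Ccl2 and Ccl7 rose by 5.50 ± 0.47 and 5.20 ± 0.24 (adjusted p = 4.0e-14 and 7.9e-24), and the neutrophil chemokine gene Cxcl2 by 4.89 ± 0.69. In the cytokine and acute inflammation list 27 of 41 members rose and 1 fell (29 and 1 adjusted over the list alone). Tested as a list, cytokine genes had a camera adjusted p = 2.4e-12 (adjusted p = 0.0504 with an estimated correlation). In the interferon response list 33 of 35 members rose and 0 fell (33 and 0 adjusted over the list alone), with Isg15 at 3.15 ± 0.37 and Herc6 at 2.80 ± 0.25. Interferon response genes had a camera adjusted p = 1.2e-15, and adjusted p = 0.0896 with an estimated correlation. Of the neutrophil genes 15 of 19 members rose and 0 fell (15 and 0 adjusted over the list alone), with the granulocyte colony-stimulating factor receptor Csf3r at 3.76 ± 0.33 and the inhibitory receptor Lilrb4 at 4.18 ± 0.29. For neutrophil genes, camera gave adjusted p = 7.9e-12, and adjusted p = 0.0288 with an estimated correlation. In the macrophage and dendritic cell list 20 of 27 members rose and 0 fell (21 and 0 adjusted over the list alone), with the Fc receptor genes Fcgr1a at 2.80 ± 0.17 and Fcer1g at 2.61 ± 0.19. The test of macrophage and dendritic cell genes by camera gave adjusted p = 1.3e-14, and adjusted p = 0.0824 with an estimated correlation. Among lymphocyte genes 22 of 35 members rose and 0 fell (23 and 1 adjusted over the list alone). Lymphocyte genes had a camera adjusted p = 1.5e-09, and adjusted p = 0.159 with an estimated correlation. Genes of cytotoxic lymphocytes were among them, with granzyme B (Gzmb) at 3.12 ± 0.24, Cd8a at 2.11 ± 0.20 and Nkg7 at 1.89 ± 0.20. Cxcl13, a chemokine gene of another kind that attracts B cells, fell by 3.59 ± 0.46 (adjusted p = 6.7e-09). In the list of class II histocompatibility genes 3 of 8 members rose and 0 fell (3 and 0 adjusted over the list alone). For class II genes, camera gave adjusted p = 0.0994, and adjusted p = 0.645 with an estimated correlation. In the endothelium and blood list 1 of 17 members rose and 0 fell (0 and 0 adjusted over the list alone), and in the fibroblast, cartilage and bone list 1 of 37 members rose and 0 fell (1 and 0 adjusted over the list alone). The test of endothelium and fibroblast genes by camera gave adjusted p = 0.333 and 0.668, and adjusted p = 0.85 and 0.942 with an estimated correlation.

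Genes of growth control, cell division and metabolism changed on the same arrays. Sprr1b rose by 5.50 ± 0.40, Areg by 4.86 ± 0.32, the stromelysin gene Mmp3 by 5.26 ± 0.39 and Fst, which encodes the activin antagonist follistatin, by 4.65 ± 0.25. In the growth factor receptor ligand and immediate early gene list 16 of 31 members rose and 2 fell (17 and 2 adjusted over the list alone), with Fosl1 at 3.32 ± 0.21 and Hbegf at 2.30 ± 0.18. Growth factor and immediate early genes had a camera adjusted p = 2.8e-08, and adjusted p = 0.0686 with an estimated correlation. In the wound repair and matrix list 18 of 39 members rose and 3 fell (19 and 3 adjusted over the list alone). For wound repair genes, camera gave adjusted p = 6.6e-05, and adjusted p = 0.159 with an estimated correlation. The mitosis list had 47 of 51 members higher (47 higher and 1 lower when adjusted over the list alone) and the S phase list 35 of 37 (35 higher and 0 lower when adjusted over the list alone). The test of mitosis and S phase genes by camera gave adjusted p = 1.3e-34 and 8.5e-20, and adjusted p = 0.0288 and 0.0326 with an estimated correlation. Of the p53 targets 13 of 24 members rose and 6 fell (13 and 6 adjusted over the list alone), with Gadd45a at 1.78 ± 0.13. P53 target genes had a camera adjusted p = 0.00133, and adjusted p = 0.0896 with an estimated correlation. In the unfolded protein and integrated stress response list 15 of 26 members rose and 2 fell (15 and 2 adjusted over the list alone), with Ddit3 at 1.32 ± 0.16, while Herpud1, a target of the unfolded protein response, was lower at -0.71 ± 0.10. For stress response genes, camera gave adjusted p = 0.00195, and adjusted p = 0.138 with an estimated correlation. In the Nrf2 and glutathione list, whose members went both ways, 9 of 36 members rose and 13 fell (9 and 13 adjusted over the list alone). The test of Nrf2 and glutathione genes by camera gave adjusted p = 0.405, and adjusted p = 0.85 with an estimated correlation. Hmox1 was at 2.02 ± 0.22 and Srxn1 at 1.86 ± 0.18, against glutathione reductase (Gsr) at -1.22 ± 0.16, the glutathione transferase Gsta3 at -1.02 ± 0.13 and Nqo1 at -0.30 ± 0.08. Enzymes that oxidise formaldehyde and other aldehydes were mostly lower: 2 of 18 members rose and 10 fell (3 and 11 adjusted over the list alone), with Aldh2 at -1.26 ± 0.12 and Aldh1a1 at -0.76 ± 0.07. Aldehyde oxidation genes had a camera adjusted p = 0.0113, and adjusted p = 0.159 with an estimated correlation. Adh5, the glutathione-dependent formaldehyde dehydrogenase, did not pass at -0.23 (adjusted p = 0.09). Of the P450 and xenobiotic metabolism genes 1 of 37 members rose and 19 fell (1 and 20 adjusted over the list alone), with Fmo1 at -2.38 ± 0.30 and Cyp4b1 at -1.78 ± 0.17. For P450 and xenobiotic genes, camera gave adjusted p = 4.9e-07, and adjusted p = 0.0288 with an estimated correlation. In the ciliated cell list 1 of 52 members rose and 30 fell (1 and 32 adjusted over the list alone). The test of ciliated cell genes by camera gave adjusted p = 6.3e-06, and adjusted p = 0.529 with an estimated correlation. The beta-actin difference was 2.47 ± 0.08 (SD, n = 4) at 15 ppm against 1.71 ± 0.20 at 0 ppm.

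**Figure D2:**
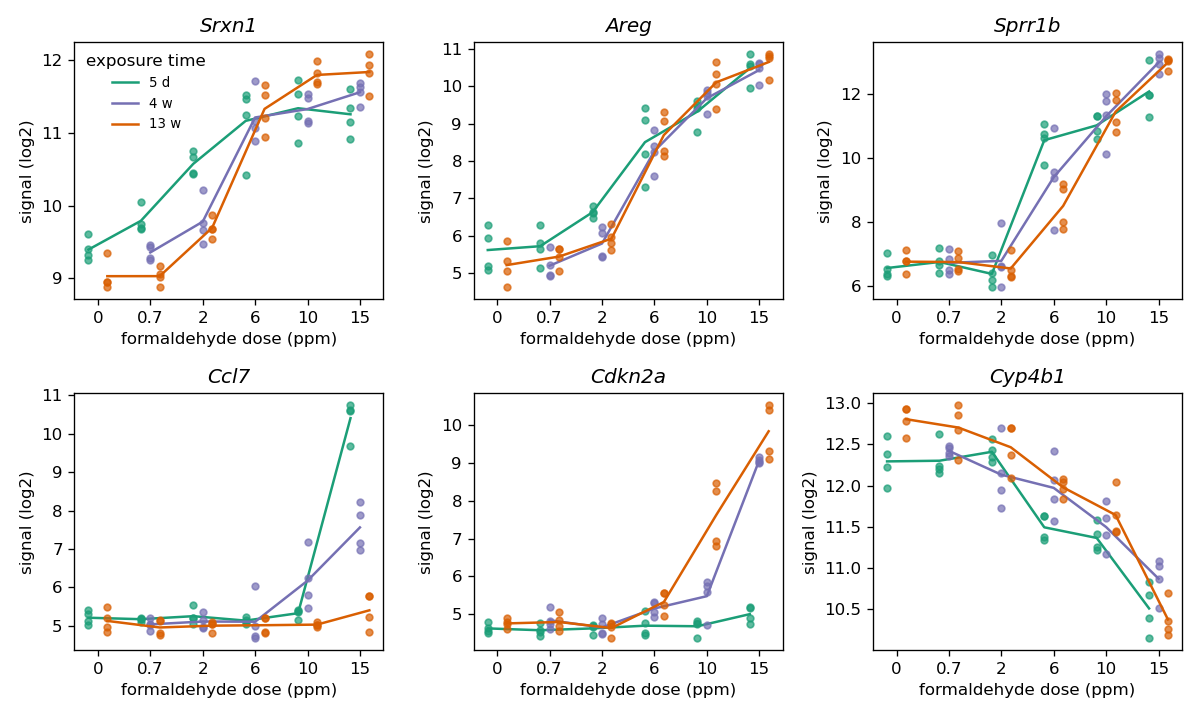
Signal on the log2 scale of 6 genes in every array (points, n = 4 per group) by formaldehyde dose in ppm and exposure time, with group means joined by lines. Srxn1, Areg and Sprr1b were higher than the reference at 6, 10 and 15 ppm at each time, Ccl7 was 5.20 higher at 15 ppm after 5 d, Cdkn2a was 5.08 higher at 15 ppm after 13 w, and Cyp4b1 was -2.43 there.

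After 13 w at 2 ppm a single gene passed, Cdk12, a kinase that acts on RNA polymerase II, at 0.82 ± 0.13 (adjusted p = 0.00128). Of the genes called at 2 ppm after 5 d, none passed at 13 w, and that difference between times was not tested for single genes. Olfactory epithelium genes had a median change of 1.01 with 0 of 28 called (0 higher and 0 lower when adjusted over the list alone). Olfactory genes had a camera adjusted p = 6.2e-11, and adjusted p = 0.764 with an estimated correlation. Fibroblast, cartilage and bone genes had a median of -0.75 with 0 of 37 called (0 higher and 2 lower when adjusted over the list alone). For fibroblast genes, camera gave adjusted p = 1.5e-09, and adjusted p = 0.764 with an estimated correlation. The olfactory marker protein gene Omp itself was at 1.17 (adjusted p = 0.504), and the mean of the olfactory list was 9.90 ± 0.43 (SD, n = 4) against 8.97 ± 0.99 at 0 ppm. The count of 1 went to 0 with 0.7 ppm as the reference, with the mean of all probe sets or without the arrays that lack an RNA integrity number, and to 66 with array weights. With adjustment over all contrasts, which shares its threshold with the high doses, it went to 217. It was 3 without 0 ppm animal 229 and 2 without 0 ppm animal 226 or 2 ppm animal 290.

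At 6 ppm after 13 w, 1072 genes were higher and 665 lower than at 0 ppm, 347 of them by at least 1.5-fold. Areg rose by 3.48 ± 0.32 (adjusted p = 2.5e-11), Krt12 by 2.83 ± 0.42, Serpinb2 by 2.74 ± 0.44 and Srxn1 by 2.30 ± 0.18 (adjusted p = 6.4e-14), while Uts2r fell by 2.08 ± 0.31 and the angiopoietin gene Angpt1 by 1.30 ± 0.20. In the mitosis list 41 of 51 members rose and 0 fell (45 and 0 adjusted over the list alone), with Ect2, which is needed for cytokinesis, at 1.12 ± 0.13. The test of mitosis genes by camera gave adjusted p = 3.0e-39, and adjusted p = 0.0431 with an estimated correlation. Among Nrf2 and glutathione genes 14 of 36 members rose and 2 fell (15 and 3 adjusted over the list alone), and among heat shock genes 9 of 22 members rose and 0 fell (9 and 0 adjusted over the list alone). Nrf2 and glutathione and heat shock genes had a camera adjusted p = 6.2e-08 and 1.1e-06, and adjusted p = 0.164 and 0.0761 with an estimated correlation. In the squamous differentiation list 11 of 37 members rose and 0 fell (14 and 0 adjusted over the list alone). For squamous differentiation genes, camera gave adjusted p = 2.2e-08, and adjusted p = 0.352 with an estimated correlation. In the P450 and xenobiotic metabolism list 1 of 37 members rose and 7 fell (1 and 8 adjusted over the list alone), with the P450 reductase gene Por at -0.84 ± 0.10. The test of P450 and xenobiotic genes by camera gave adjusted p = 7.1e-05, and adjusted p = 0.0761 with an estimated correlation. The share of called genes that was higher, 61.7%, became 38.1% with each array centred on its median.

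At 10 ppm after 13 w, 1966 genes were higher and 1784 lower, 1009 by at least 1.5-fold. Areg rose by 4.89 ± 0.32 (adjusted p = 1.6e-17) and Sprr1b by 4.66 ± 0.40. The squamous differentiation list had 26 of 37 members higher, with 29 higher and 0 lower when adjusted over the list alone. Squamous differentiation genes had a camera adjusted p = 9.2e-14, and adjusted p = 0.129 with an estimated correlation. In the mitosis list 47 of 51 members rose and 0 fell (47 and 0 adjusted over the list alone), and in the S phase list 35 of 37 members rose and 0 fell (35 and 0 adjusted over the list alone). For mitosis and S phase genes, camera gave adjusted p = 2.1e-50 and 7.6e-23, and adjusted p = 0.0109 and 0.0347 with an estimated correlation. In the heat shock list 14 of 22 members rose and 0 fell (14 and 1 adjusted over the list alone), with the small heat shock protein Hspb1 at 1.53 ± 0.22. The test of heat shock genes by camera gave adjusted p = 1.9e-06, and adjusted p = 0.0577 with an estimated correlation. Decreases included the casein gene Csn3 at -3.24 ± 0.89 and the potassium channel subunit Kcne1 at -2.23 ± 0.80. Both also varied between arrays of a group. They lay at the gland and stroma end of the largest component of the differences between arrays of 1 group, described below. A varying share of such tissue was therefore not separated from the dose for these genes. In the fibroblast, cartilage and bone list 0 of 37 members rose and 9 fell (0 and 8 adjusted over the list alone), with the collagen genes Col1a1 at -1.33 ± 0.40 and Col1a2 at -1.23 ± 0.34. Fibroblast genes had a camera adjusted p = 7.9e-04, and adjusted p = 0.674 with an estimated correlation.

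At 15 ppm after 13 w, 3344 genes were higher and 2934 lower than at 0 ppm, 2528 of them by at least 1.5-fold. Sprr1b rose by 6.20 ± 0.40 (adjusted p = 1.6e-18), Areg by 5.43 ± 0.32 and Krt12 by 5.24 ± 0.42. Among genes of the cornified envelope and stratified epithelium, Sprr3 rose by 4.02 ± 0.65, suprabasin (Sbsn) by 4.53 ± 0.71, dermokine (Dmkn) by 4.51 ± 0.56 and the keratinocyte transglutaminase Tgm1 by 3.94 ± 0.35. In the squamous differentiation list 34 of 37 members rose and 0 fell (34 and 0 adjusted over the list alone), with involucrin (Ivl) at 3.04 ± 0.28 and Krt13 at 1.58 ± 0.43. For squamous differentiation genes, camera gave adjusted p = 3.7e-17, and adjusted p = 0.113 with an estimated correlation. Cdkn2a, which encodes inhibitors of the cell cycle, rose by 5.08 ± 0.24 (adjusted p = 2.4e-23), and Cdkn1a by 2.19 ± 0.14. Proliferation genes rose as well: in the mitosis list 48 of 51 members rose and 1 fell (48 and 1 adjusted over the list alone), with the proliferation marker Mki67 at 2.44 ± 0.23. The test of mitosis genes by camera gave adjusted p = 1.9e-40, and adjusted p = 0.0328 with an estimated correlation. In the S phase list 36 of 37 members rose and 0 fell (36 and 0 adjusted over the list alone). S phase genes had a camera adjusted p = 4.2e-23, and adjusted p = 0.0328 with an estimated correlation. In the ribosome biogenesis list 31 of 32 members rose and 0 fell (31 and 0 adjusted over the list alone), with Nop58 at 1.07 ± 0.09. For ribosome biogenesis genes, camera gave adjusted p = 2.0e-17, and adjusted p = 0.113 with an estimated correlation. Of the DNA repair genes 21 of 39 members rose and 3 fell (23 and 3 adjusted over the list alone), with Exo1 at 1.70 ± 0.14 and Fancd2 at 1.32 ± 0.12. The test of DNA repair genes by camera gave adjusted p = 7.4e-05, and adjusted p = 0.118 with an estimated correlation. Of the p53 targets 14 of 24 members rose and 4 fell (15 and 4 adjusted over the list alone), where Tp53i11 was lower at -1.07 ± 0.09. P53 target genes had a camera adjusted p = 0.00191, and adjusted p = 0.118 with an estimated correlation. Among Nrf2 and glutathione genes 19 of 36 members rose and 4 fell (22 and 4 adjusted over the list alone), with Slc7a11 at 3.03 ± 0.25 and Nqo1 at 0.52 ± 0.08. For Nrf2 and glutathione genes, camera gave adjusted p = 2.1e-04, and adjusted p = 0.36 with an estimated correlation. In the basal cell list 14 of 22 members rose and 3 fell (14 and 3 adjusted over the list alone), with Krt14 at 1.37 ± 0.10 and Krt5 at 1.13 ± 0.15. The test of basal cell genes by camera gave adjusted p = 0.00486, and adjusted p = 0.366 with an estimated correlation. Of the unfolded protein and integrated stress response genes 11 of 26 members rose and 5 fell (13 and 5 adjusted over the list alone), with the serine synthesis genes Psat1 at 1.40 ± 0.08 and Phgdh at 1.33 ± 0.14 among them. Stress response genes had a camera adjusted p = 0.0341, and adjusted p = 0.37 with an estimated correlation.

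Genes lower at 15 ppm after 13 w included members of the ciliated cell, secretory cell, class II and lymphocyte lists. In the ciliated cell list 1 of 52 members rose and 44 fell (1 and 45 adjusted over the list alone), with the ciliogenesis regulator Foxj1 at -0.90 ± 0.17, while Ccno, which acts in the multiplication of centrioles, was higher at 1.05 ± 0.18. For ciliated cell genes, camera gave adjusted p = 6.3e-08, and adjusted p = 0.441 with an estimated correlation. In the secretory and goblet cell list 3 of 42 members rose and 15 fell (3 and 15 adjusted over the list alone), with the polymeric immunoglobulin receptor Pigr at -1.55 ± 0.21, and the mucin gene Muc5ac was at -0.15 (adjusted p = 0.862). The test of secretory cell genes by camera gave adjusted p = 0.00382, and adjusted p = 0.118 with an estimated correlation. Of the P450 and xenobiotic metabolism genes 3 of 37 members rose and 17 fell (3 and 18 adjusted over the list alone), with Cyp4b1 at -2.43 ± 0.17, Fmo1 at -2.41 ± 0.30 and Por at -1.27 ± 0.10. P450 and xenobiotic genes had a camera adjusted p = 1.6e-05, and adjusted p = 0.0418 with an estimated correlation. In the aldehyde oxidation list 3 of 18 members rose and 10 fell (4 and 10 adjusted over the list alone), with Aldh2 at -0.89 ± 0.12 and the one-carbon enzyme Shmt2 higher at 1.20 ± 0.13. For aldehyde oxidation genes, camera gave adjusted p = 0.12, and adjusted p = 0.441 with an estimated correlation. Among class II histocompatibility genes 0 of 8 members rose and 6 fell (0 and 6 adjusted over the list alone), with the invariant chain Cd74 at -0.93 ± 0.13. The test of class II genes by camera gave adjusted p = 0.00486, and adjusted p = 0.441 with an estimated correlation. In the lymphocyte list 0 of 35 members rose and 17 fell (0 and 17 adjusted over the list alone), with Cd3g at -0.89 ± 0.14 and the B cell kinase Blk at -0.75 ± 0.13. Lymphocyte genes had a camera adjusted p = 0.00191, and adjusted p = 0.524 with an estimated correlation. Of the neutrophil genes 3 of 19 members rose and 1 fell (2 and 1 adjusted over the list alone), and of the macrophage and dendritic cell genes 1 of 27 members rose and 7 fell (1 and 7 adjusted over the list alone). For neutrophil and macrophage and dendritic cell genes, camera gave adjusted p = 0.934 and 0.0732, and adjusted p = 0.971 and 0.717 with an estimated correlation. Among interferon response genes 4 of 35 members rose and 7 fell (2 and 4 adjusted over the list alone), and among cytokine genes 12 of 41 members rose and 4 fell (12 and 4 adjusted over the list alone). The test of interferon response and cytokine genes by camera gave adjusted p = 0.532 and 0.253, and adjusted p = 0.894 and 0.755 with an estimated correlation. In the fibroblast, cartilage and bone list 1 of 37 members rose and 13 fell (1 and 10 adjusted over the list alone). Fibroblast genes had a camera adjusted p = 0.00304, and adjusted p = 0.688 with an estimated correlation. In the olfactory list 0 of 28 members rose and 1 fell (0 and 0 adjusted over the list alone), and in the endothelium and blood list 0 of 17 members rose and 0 fell (0 and 0 adjusted over the list alone). For olfactory and endothelium genes, camera gave adjusted p = 0.277 and 0.237, and adjusted p = 0.843 and 0.755 with an estimated correlation. In the skeletal muscle list 0 of 19 members rose and 2 fell (0 and 1 adjusted over the list alone), and in the nerve and glia list 1 of 15 members rose and 1 fell (1 and 1 adjusted over the list alone). The test of skeletal muscle and nerve and glia genes by camera gave adjusted p = 0.532 and 0.532, and adjusted p = 0.837 and 0.717 with an estimated correlation.

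**Figure D3:**
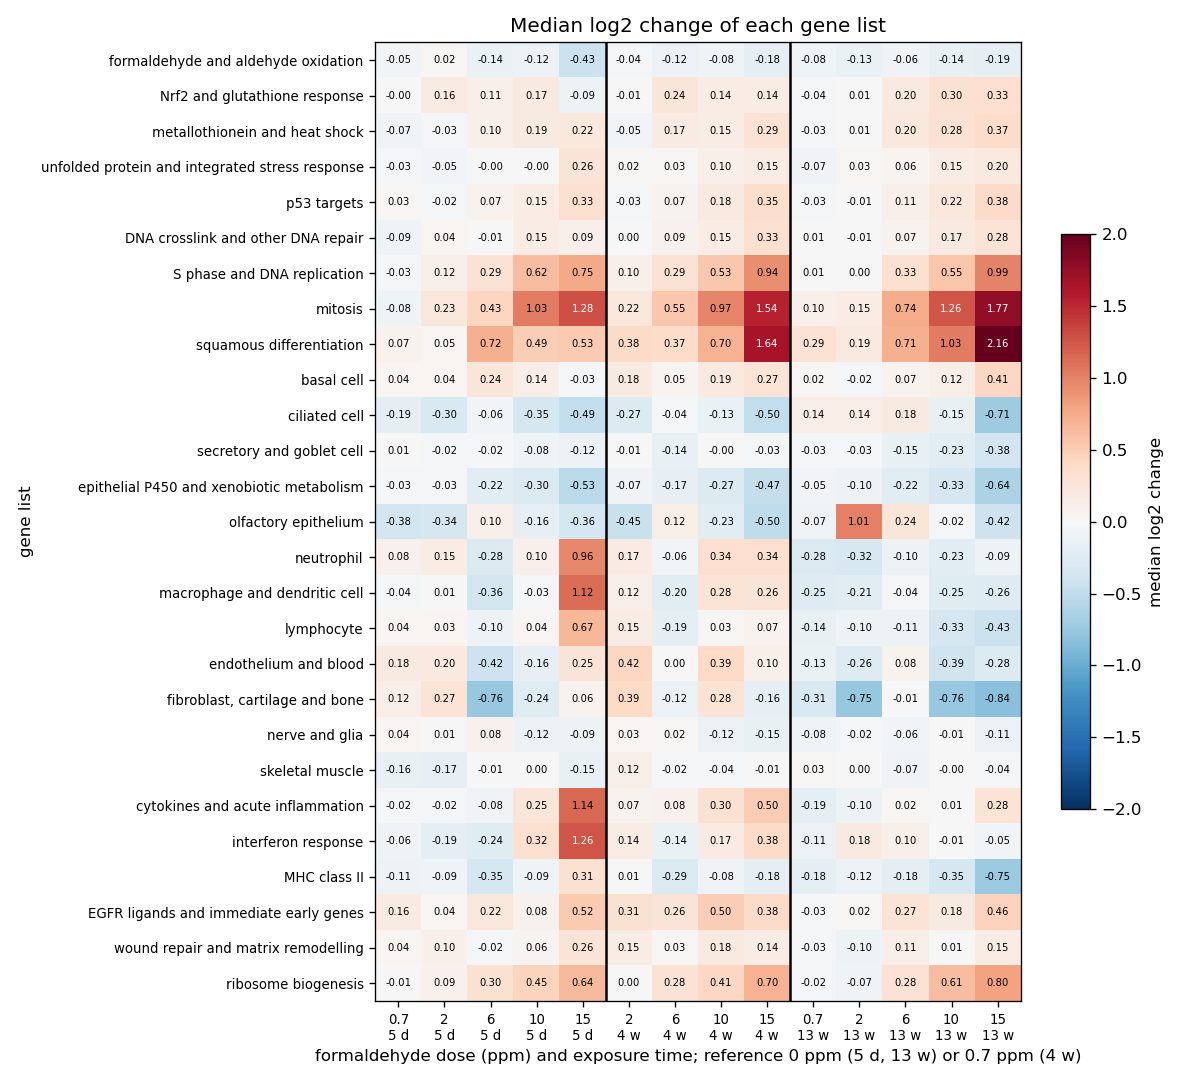
Median log2 change over the measured members of each of the 27 gene lists (vertical axis) in each comparison with the reference (horizontal axis, dose in ppm by exposure time), on a colour scale from -2 to 2. The mitosis list runs from 0.23 at 2 ppm to 1.28 at 15 ppm after 5 d, and the squamous differentiation list reaches 2.16 at 15 ppm after 13 w.

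At 4 w, 2 ppm differed from 0.7 ppm in 3 genes: the homeobox gene Msx2 at 1.27 ± 0.26, the laminin gene Lama1 at 0.47 ± 0.09 and Ube2b at -0.45 ± 0.09 (adjusted p = 0.0394 for each). At 6 ppm, 291 genes were higher and 176 lower, with Areg at 3.07 ± 0.32 (adjusted p = 2.3e-09), Sprr1b at 2.67 ± 0.40 and Serpinb2 at 2.65 ± 0.44. In the Nrf2 and glutathione list 13 of 36 members rose and 0 fell (19 and 0 adjusted over the list alone), and in the mitosis list 33 of 51 members rose and 0 fell (43 and 0 adjusted over the list alone). Nrf2 and glutathione and mitosis genes had a camera adjusted p = 2.3e-16 and 2.7e-43, and adjusted p = 0.0367 and 0.0259 with an estimated correlation. At 10 ppm, 1284 genes were higher and 818 lower, with Areg at 4.48 ± 0.32 and Mmp3 at 3.65 ± 0.39. Among neutrophil genes 7 of 19 members rose and 0 fell (7 and 0 adjusted over the list alone), with S100a9 at 2.41 ± 0.50. For neutrophil genes, camera gave adjusted p = 9.2e-04, and adjusted p = 0.259 with an estimated correlation. Among cytokine genes 14 of 41 members rose and 1 fell (16 and 1 adjusted over the list alone), with Ccl2 at 2.43 ± 0.47. The test of cytokine genes by camera gave adjusted p = 2.9e-05, and adjusted p = 0.245 with an estimated correlation. The count of 3 at 2 ppm was 0 without 0.7 ppm animals 243 or 250 or 2 ppm animals 276 or 277, and 1 without 0.7 ppm animals 242 or 245 or 2 ppm animal 272. It was 0 with array weights, cyclic loess or median centring. Against the mean of the 0 ppm groups of 5 d and 13 w, or with adjustment over all contrasts, it was far higher, as given in the section on processing. The count of 467 at 6 ppm was 201 with the 4 w arrays fitted alone, 304 and 275 without 0.7 ppm animals 243 and 245, and 133 without 6 ppm animal 310; against the mean of the 0 ppm groups of 5 d and 13 w it was 1729.

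At 15 ppm after 4 w, 3028 genes were higher and 2290 lower than at 0.7 ppm, 1745 by at least 1.5-fold. Sprr1b rose by 6.23 ± 0.40 (adjusted p = 4.0e-18), Areg by 5.23 ± 0.32, Cdkn2a by 4.23 ± 0.24 (adjusted p = 1.3e-19) and Cxcl2 by 4.18 ± 0.69, and Cxcl13 fell by 2.93 ± 0.46. In the squamous differentiation list 30 of 37 members rose and 0 fell (30 and 0 adjusted over the list alone), and in the mitosis list 48 of 51 members rose and 1 fell (48 and 1 adjusted over the list alone). Squamous differentiation and mitosis genes had a camera adjusted p = 1.8e-14 and 9.6e-45, and adjusted p = 0.161 and 0.0217 with an estimated correlation. In the cytokine list 22 of 41 members rose and 1 fell (22 and 1 adjusted over the list alone), and in the interferon response list 13 of 35 members rose and 0 fell (13 and 0 adjusted over the list alone). For cytokine and interferon response genes, camera gave adjusted p = 9.1e-06 and 0.00357, and adjusted p = 0.225 and 0.584 with an estimated correlation. Among macrophage and dendritic cell genes 9 of 27 members rose and 0 fell (9 and 0 adjusted over the list alone). The test of macrophage and dendritic cell genes by camera gave adjusted p = 0.0291, and adjusted p = 0.646 with an estimated correlation. In the ciliated cell list 1 of 52 members rose and 33 fell (1 and 42 adjusted over the list alone), with the axonemal dynein gene Dnah7 at -0.91 ± 0.22. Ciliated cell genes had a camera adjusted p = 8.1e-08, and adjusted p = 0.461 with an estimated correlation. In the P450 list 2 of 37 members rose and 16 fell (2 and 17 adjusted over the list alone). For P450 and xenobiotic genes, camera gave adjusted p = 1.3e-05, and adjusted p = 0.0404 with an estimated correlation. Aldh2 fell by 0.74 ± 0.12.

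The response to 15 ppm against 0 ppm differed between 13 w and 5 d in 2175 genes, 1309 with a higher and 866 with a lower response at 13 w, and 1158 of them differed by at least 1.5-fold. Lower responses at 13 w included those of the chemokine gene Ccl7 at -4.92 ± 0.34 (adjusted p = 7.5e-16), the stromelysin gene Mmp3 at -4.69 ± 0.55, Cxcl11 at -4.68 ± 0.72, Cxcl10 at -4.58 ± 0.76 and Ccl2 at -4.36 ± 0.67. The response of macrophage and dendritic cell genes was lower in 22 of 27 members (0 and 25 adjusted over the list alone), that of lymphocyte genes in 27 of 35 (0 and 28 adjusted over the list alone), and that of interferon genes in 30 of 35 (0 and 33 adjusted over the list alone). The test of macrophage and dendritic cell, lymphocyte and interferon response genes by camera gave adjusted p = 3.9e-29, 1.2e-26 and 1.1e-23, and adjusted p = 0.0153, 0.0197 and 0.049 with an estimated correlation. For neutrophil genes it was lower in 13 of 19 (0 and 14 adjusted over the list alone), for cytokine genes in 19 of 41 (1 and 20 adjusted over the list alone) and for class II histocompatibility genes in 7 of 8 (0 and 7 adjusted over the list alone). Neutrophil, cytokine and class II genes had a camera adjusted p = 1.4e-16, 2.2e-13 and 7.7e-08, and adjusted p = 0.0132, 0.046 and 0.117 with an estimated correlation. Higher responses included those of Cdkn2a at 4.70 ± 0.34 (adjusted p = 2.6e-15), C20h6orf15 at 4.21 ± 1.12, the beta-defensin gene Defb4 at 4.18 ± 1.12, Akr1c3 at 3.49 ± 0.79 and C18h5orf46 at 3.44 ± 0.99. The response was higher at 13 w in 29 of 37 squamous differentiation genes (34 and 0 adjusted over the list alone). For squamous differentiation genes, camera gave adjusted p = 1.1e-17, and adjusted p = 0.0836 with an estimated correlation. It was also higher in 23 of 51 mitosis genes (28 and 0 adjusted over the list alone) and in 19 of 36 Nrf2 and glutathione genes (21 and 0 adjusted over the list alone). The test of mitosis and Nrf2 and glutathione genes by camera gave adjusted p = 2.3e-10 and 4.0e-10, and adjusted p = 0.267 and 0.0836 with an estimated correlation. At 0 ppm, 24 of the mitosis genes were lower at 13 w than at 5 d, so that part of their difference in response lies in the reference, as for Ect2 with a response difference of 1.00 ± 0.18 and a change of -0.78 at 0 ppm. In the Nrf2 and glutathione list the response of Nqo1 differed by 0.82 ± 0.12 and that of Gsr by 1.47 ± 0.23, and both genes were below their 0 ppm level after 5 d. Differences in the response of Aldh2 (0.37, adjusted p = 0.134) and Foxj1 (-0.56, adjusted p = 0.111) did not pass.

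At 10 ppm the response differed between 13 w and 5 d in 1 gene, Cdkn2a, at 2.81 ± 0.34 (adjusted p = 7.6e-07). At 6 ppm limma called 0 genes with a different response, and 1494 had an unadjusted p under 0.05, so that genes called at 6 ppm at 1 time alone were not shown to differ between times. With array weights these counts were 31 and 110, and at 6 ppm the count was 40 with each array centred on its median. With adjustment over all contrasts, which shares its threshold with the 15 ppm contrasts, they were 131 and 289. The count at 10 ppm was 7 without 10 ppm 13 w animal 348, and at 6 ppm 1 without 0 ppm 13 w animal 229 and 4 without 0 ppm 5 d animal 210. Against 0.7 ppm, the 15 ppm response differed between 4 w and 5 d in 490 genes, 225 with a higher and 265 with a lower response at 4 w, with Cdkn2a at 3.80 ± 0.34, Sprr3 at 3.56 ± 0.92, Cxcl11 at -3.51 ± 0.72 and Gzmb at -2.44 ± 0.34. It was lower in 13 of 27 macrophage and dendritic cell genes (0 and 19 adjusted over the list alone) and higher in 10 of 37 squamous differentiation genes (28 and 0 adjusted over the list alone). Macrophage and dendritic cell and squamous differentiation genes had a camera adjusted p = 1.1e-21 and 9.2e-19, and adjusted p = 0.0777 and 0.093 with an estimated correlation. Between 13 w and 4 w it differed in 9 genes, among them Ccl7 at -2.08 ± 0.34, Mmp3 at -2.92 ± 0.55, the macrophage gene Lst1 at -0.98 ± 0.21 and, with a higher response at 13 w, Qrich1 at 0.92 ± 0.19. The count of 490 was 847 with the beta-actin covariate, and that of 9 was 104 with array weights. The count of 9 became 3 to 5 without 0.7 ppm 13 w animals 257, 258 or 259, 0.7 ppm 4 w animals 245 or 250, 15 ppm 13 w animal 375 or 15 ppm 4 w animal 368, 14 without 15 ppm 4 w animal 365 and 18 without 0.7 ppm 13 w animal 260.

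In unexposed animals, 89 genes were higher and 230 lower at 13 w than at 5 d, 74 of them by at least 1.5-fold. These groups also differ in the code of their titles, which cannot be separated from time here. In the mitosis list 0 of 51 members rose and 24 fell (1 and 38 adjusted over the list alone), with Ect2 at -0.78 ± 0.13 (adjusted p = 3.7e-04) and Cdk1 at -0.67 ± 0.13. For mitosis genes, camera gave adjusted p = 2.4e-28, and adjusted p = 0.18 with an estimated correlation. In the S phase list 0 of 37 members rose and 3 fell (0 and 15 adjusted over the list alone). The test of S phase genes by camera gave adjusted p = 5.0e-08, and adjusted p = 0.402 with an estimated correlation. The growth-associated protein gene of immature neurons, Gap43, which is in the olfactory list, fell by 2.08 ± 0.56, and the peripherin gene Prph by 1.47 ± 0.31. The immunoglobulin joining chain gene Jchain rose by 1.88 ± 0.50 and Ighl2 by 1.68 ± 0.42, and troponin Tnnt1 by 1.64 ± 0.28. The share of called genes that was higher, 27.9%, became 85.1% with each array centred on its median, which moved the median of all genes from -0.02 to 0.07, and 50.6% with cyclic loess. The count of 319 was 180 and 88 without 0 ppm 13 w animals 225 and 230, 87 and 108 without 0 ppm 5 d animals 207 and 208, and 1242 with array weights.

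Genes called at 5 d were compared with those called at 13 w, whose groups shared no array. The fit gave each gene 1 spread for both times, so the calls of the times are not fully independent. At 15 ppm, 1776 of the 2598 genes higher at 5 d (68.4%) were also higher at 13 w, against 611 if the calls were independent, and 1788 of the 2766 lower genes (64.6%) were also lower, against 571. In the opposite direction, 70 genes were higher at 5 d and lower at 13 w, and 94 the reverse. At 10 ppm, 1148 of 1386 higher genes (82.8%, 192 if independent) and 676 of 823 lower genes (82.1%, 103 if independent) were shared, and at 6 ppm 351 of 503 higher (69.8%, 37.9 if independent) and 245 of 753 lower (32.5%, 35.2 if independent). A set of 162 genes was higher and 61 were lower in all 9 comparisons at 6, 10 and 15 ppm. These 223 genes became 101 (84 higher, 17 lower) without 6 ppm 4 w animal 310 and 144 (98 higher, 46 lower) without 6 ppm 5 d animal 300. Doses of 1 time shared their reference arrays, so their overlap was set against fits in which each dose used its own 2 of the 4 reference arrays, and the covariance of their changes against simulated unchanged groups. Fits with fewer reference arrays also have less power, so a fall in shared genes need not all come from the shared reference. At 13 w, 10 and 15 ppm shared 1895 higher genes, against 462 if independent and 1348.5 on average with split references, and the covariance of their log2 changes was 0.190 against 0.0126 simulated. At 5 d, 6 and 10 ppm shared 445 higher genes, against 49.0 if independent and 155.5 with split references, with a covariance of 0.0496 against 0.0138 simulated.

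The genes called at 15 ppm at 1 time were followed as a set at the lower doses of the other time, with fry and adjustment over 32 tests. The 3344 genes higher and 2934 lower at 15 ppm after 13 w had median changes at 5 d of -0.03 (adjusted p = 0.503) and -0.06 (adjusted p = 0.193) at 0.7 ppm, and of 0.04 (adjusted p = 0.355) and -0.07 (adjusted p = 0.0560) at 2 ppm. At 6 ppm after 5 d the medians were 0.12 (adjusted p = 0.00436) and -0.18 (adjusted p = 4.4e-06), and at 10 ppm 0.22 (adjusted p = 3.6e-07) and -0.22 (adjusted p = 3.5e-07). The 2598 higher and 2766 lower genes of 15 ppm after 5 d had medians at 13 w of -0.02 (adjusted p = 0.854) and -0.05 (adjusted p = 0.202) at 2 ppm, 0.15 (adjusted p = 8.8e-04) and -0.09 (adjusted p = 0.0107) at 6 ppm, and 0.25 (adjusted p = 1.8e-07) and -0.25 (adjusted p = 1.6e-08) at 10 ppm. At 4 w against 0.7 ppm, the lower set of 5 d had a median of -0.08 at 2 ppm (adjusted p = 0.0481) and the lower set of 13 w a median of -0.08 (adjusted p = 0.0560). Camera with the preset correlation, the alternative test, called more of these sets at low dose. At 2 ppm after 5 d its adjusted p was 1.1e-08 for the higher and 2.1e-14 for the lower set, and at 2 ppm after 4 w 8.3e-16 for the lower set of 5 d and 3.1e-12 for that of 13 w. For the lower sets it was 0.00481 at 0.7 ppm after 5 d and 0.00293 at 2 ppm after 13 w, where the higher set had 0.297. At 0.7 ppm after 13 w the sets of 5 d had medians of -0.03 for the higher genes (fry adjusted p = 0.611, camera adjusted p = 0.00480) and 0.01 for the lower genes (fry adjusted p = 0.854, camera adjusted p = 0.297), both against the direction at 15 ppm. Whether 2 ppm moved these sets thus depends on the test.

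Genes of the olfactory lining lay at 1 end of the largest component of the differences between arrays of 1 group. The first component of the variation within groups held 35.1% of it and separated olfactory neuron genes, such as the channel gene Cnga2 and the G protein gene Gnal, which were chosen after their loadings were seen, from gland and stroma genes. The mean of the olfactory list had an SD of 0.13 to 1.16 within groups of 4, although the tissue labels describe the olfactory lining as removed, and Omp did not pass in any dose comparison, with changes from -0.53 at 2 ppm after 4 w to 1.17 at 2 ppm after 13 w.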

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

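The tests below of RNA quality, of carried-over tissue, of a lower epithelial share and of entering immune cells for the immune genes at 15 ppm, and both tests of the olfactory genes, were chosen after the results were seen.

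At 2 ppm after 5 d, Srxn1, Hmox1, Slc7a11 and Maff rose by 1.19 ± 0.10 (SE, n = 4 per group) on average. The lowest mean without 1 array was 1.12, but the genes were chosen as called on these arrays, which limits that test of a single array. RNA quality or tissue makeup as the whole cause is argued against by means of 1.21 with the beta-actin covariate and 1.13 with the olfactory and fibroblast means as covariates. These tests reach only as far as the covariates measure either cause, and they use the arrays on which the genes were chosen. A response to the exposure stays open as a hypothesis: at 13 w the mean was 0.54 ± 0.07 (exact permutation p = 0.0286, the smallest that 70 arrangements allow), which lies below 0.5 of the 5 d value, but by less than its SE. At 4 w against 0.7 ppm it was 0.45 ± 0.18 (exact permutation p = 0.0571), and on the 5 d arrays, where choosing these genes raises the values, 0.70 ± 0.10 for 2 against 0.7 ppm and 0.49 ± 0.07 for 0.7 against 0 ppm, so a part tied to the 0 ppm arrays stays open. Other splits of the 8 arrays limit the count of 4 genes, as 2 of 35 splits gave as many and the highest other gave 6, so chance could not be excluded for the count itself.

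At 15 ppm after 5 d, 117 genes of the cytokine, interferon and leukocyte lists rose with a median of 1.53, and at 13 w the response was lower. The beta-actin difference was also raised at 6 ppm, where the median of these genes was -0.17, which argues against RNA quality as the cause. The lowest median without any 1 of the 8 arrays was 1.36, but the genes were chosen as called on these arrays, which limits that test. The rise is not due to carried-over blood and stroma alone, whose 54 list genes had a median of 0.14 (quartiles -0.04 to 0.33), against 1.06 (quartiles 0.45 to 1.91) for all 157 members of the immune lists. A lower epithelial share that raised the genes of every other cell type alike is argued against by the same spread. The upper quartile of 0.33 for blood and stroma lies below the lower quartile of 0.45 for the immune lists. It also lies below that of 0.43 for the 81 members of the leukocyte lists alone. Whether blood, stroma and leukocytes were carried into the suspension alike was not tested. Induction in the epithelial cells alone was not tested for the leukocyte lists, whose 81 members had a median of 0.91 (quartiles 0.43 to 1.86). Their rise is part of the pattern, and the arrays do not show which cells carried a transcript. Immune cells entering the epithelium stay open, as does induction in the epithelial cells. The 76.1% of the neutrophil, macrophage and dendritic cell list members that rose are part of the pattern and do not test entry.

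Olfactory neuron genes differed between arrays of 1 group. Their median correlation with Omp within groups was 0.945, against -0.419 for the fibroblast list, which is consistent with olfactory lining carried into the cell suspension in varying amounts, although the labels say it was discarded. Whether the exposure also altered these genes cannot be told apart from that, since 4 was the largest number of the 28 members called at 1 dose.

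The difference between exposure times was past the threshold for these genes. Between 13 w and 5 d at 15 ppm it was -4.92 for Ccl7, -4.69 for Mmp3, -4.68 for Cxcl11, -4.58 for Cxcl10 and -4.36 for Ccl2, and 4.70 for Cdkn2a, 4.21 for C20h6orf15, 4.18 for Defb4, 3.49 for Akr1c3, 3.44 for C18h5orf46, 1.47 for Gsr, 1.00 for Ect2 and 0.82 for Nqo1. At 10 ppm it was 2.81 for Cdkn2a. Between 4 w and 5 d at 15 ppm it was 3.80 for Cdkn2a, 3.56 for Sprr3, -3.51 for Cxcl11 and -2.44 for Gzmb. Between 13 w and 4 w it was -2.92 for Mmp3, -2.08 for Ccl7, -0.98 for Lst1 and 0.92 for Qrich1.

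Of 326 groups of 4 arrays behind the printed values, 22 (6.75%) held 1 array far from the other 3, where chance gives about 1 in 20. The gap as a share of the range (past Dixon's 95% critical value for 4 samples) was 0.968 for Maff at 2 ppm after 5 d, 0.967 for Pigr, 0.955 for Phgdh, 0.869 for Cd74 and 0.833 for Srxn1 at 0 ppm after 13 w. It was 0.892 for Gsr, 0.849 for Mmp3, 0.842 for Uhrf1 and 0.840 for Gsta3 at 0 ppm after 5 d. At 15 ppm it was 0.851 for Ccl7 after 5 d, 0.943 for Psat1, 0.926 for Cdkn1a and 0.869 for Areg after 13 w and 0.834 for Dnah7 after 4 w. Dnah7 at 0.7 ppm after 4 w had 0.906, Serpinb2 at 6 ppm after 4 w 0.832 and the fibroblast list mean at 0.7 ppm after 4 w 0.920. The beta-actin difference had 0.833 at 0.7 ppm after 13 w, 0.884 at 10 ppm after 5 d and 0.866 at 15 ppm after 5 d. The RNA integrity number had 0.833 at 0 ppm after 5 d and 1 at 10 ppm after 13 w.

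Among the 9780 probe sets without a gene name, which no comparison above uses, 1546 (15.8%) were called at 15 ppm after 5 d and 2170 (22.2%) after 13 w, against 26.7% and 33.5% of all probe sets.

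Other splits of the arrays were counted for every comparison. In the comparisons of 6, 10 and 15 ppm at all 3 times, 1 of 35 splits, the real one, gave as many genes. At 4 w the reference was 0.7 ppm. That share of 0.0286 is the smallest that 35 splits allow and was not adjusted over the comparisons. It argues against chance for each count but does not exclude it. The real counts and the highest others were 1256 and 55, 2209 and 734, and 5364 and 2474 after 5 d, 1737 and 27, 3750 and 846, and 6278 and 3682 after 13 w, and 467 and 124, 2102 and 280, and 5318 and 1284 after 4 w. At 0.7 ppm the splits did not argue against chance, as 35 of 35 gave as many (0 against a highest other of 1 after 5 d and of 31 after 13 w). Nor did they at 2 ppm after 13 w (4 of 35, 1 against 12) or 4 w (4 of 35, 3 against 12). The splits with 31 and 12 genes may reflect a structure of the samples other than dose, which was not tested.

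For the interactions, 100 splits that regrouped the times within each dose were counted each. At 15 ppm, 2 of 100 groupings, the real one among them, gave as many genes for 13 w and 5 d (2175, highest other 2484). For 4 w and 5 d it was also 2 of 100 (490, highest other 500). At 6 ppm it was 100 of 100 (0 against 11) and at 10 ppm 12 of 100 (1 against 1462). Regrouping the times at 1 dose can turn a difference between times, such as that of 319 genes at 0 ppm, into an interaction. These splits therefore cannot decide on chance. For 13 w and 4 w the share was under 0.05 (4 of 100, 9 against 1172), but as the count ran from 3 to 18 without 1 array, nothing is built on it. Splits that call many times the real count, as with 1172 and 1462, can follow from this regrouping of times, and their cause was not tested. For 13 w against 5 d at 0 ppm, 1 of 35 splits gave as many (319 against 7), which argues against chance but does not exclude it.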

How the results depend on the processing

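The covariates from the olfactory and fibroblast lists and the fit without the arrays that lack an RNA integrity number were chosen after the data were seen. Of the gene lists, 270 of 540 tests passed with the preset correlation, 26 with an estimated correlation and 150 with fry, and the cause of each change below was not tested unless stated. Of 1113 values of named genes, 1109 kept their direction and their side of the threshold with a trended and robust prior or with genes of low signal left out, 1090 with cyclic loess, 1085 with each array centred on its median, 1053 with the beta-actin covariate and 1035 with the RNA integrity covariate, under which 77 grew weaker. That covariate also leaves out the arrays that lack the number, and leaving them out alone kept 1059, with 54 weaker. With 0.7 ppm as the reference 517 were the same, 61 weaker and 4 stronger. Counts are given by dose and time, with int for interactions between times.

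With each array centred on its median the count was 0 at 2 ppm 4 w, 40 (0 higher, 40 lower) for int 6 ppm and 582 for time at 0 ppm. The share that was higher became 61.6% from 40.0% at 6 ppm 5 d, 38.1% from 61.7% at 6 ppm 13 w, 56.4% from 45.9% for int 4 w and 5 d, and 85.1% from 27.9% for time at 0 ppm. With cyclic loess the counts were 0 at 2 ppm 4 w and 6 for int 6 ppm, and the share higher was 51.8% at 6 ppm 5 d, 50.6% for time at 0 ppm and 38.5% from 22.2% for int 13 w and 4 w. With only genes of a highest group mean of at least 6, 0.7 ppm 5 d gave 2 and int 10 ppm 2. With the mean of all probe sets, 2 ppm 13 w and 2 ppm 4 w gave 0, int 6 ppm 1, int 10 ppm 4 and int 13 w and 4 w 22. Reversed under that mean, and no longer called, were Cngb1 at 15 ppm 4 w at -0.070 (0.31 before) and Hsp90ab1 for time at 0 ppm at 0.059 (-0.23 before).

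With every probe set by itself, which tests more features, the counts were 1 at 0.7 ppm, 8305 at 15 ppm 5 d, 4, 2689 and 10410 at 2, 6 and 15 ppm 13 w, 0 and 8577 at 2 and 15 ppm 4 w, 2 for int 6 ppm, 14 for int 13 w and 4 w and 617 for time at 0 ppm. A change of at least 1.5-fold, a stricter threshold by construction, left 226, 468 and 1740 at 6, 10 and 15 ppm 5 d, 347, 1009 and 2528 at 13 w, 1, 134, 513 and 1745 from 2 to 15 ppm 4 w, 1158 for int 15 ppm and 74 for time at 0 ppm. Adjustment over all contrasts gave 151 and 118 at 0.7 and 2 ppm 5 d, 51 and 217 at 13 w, 163 and 767 at 2 and 6 ppm 4 w, 289 and 131 for int 6 and 10 ppm, 787 for int 4 w and 5 d, 273 for int 13 w and 4 w and 715 for time at 0 ppm. This adjustment shares 1 threshold with the 15 ppm contrasts, so it does not control the share of false calls within a low-dose contrast. At 0.7 ppm 13 w, 4.40% of genes had an unadjusted p under 0.05. Array weights gave 8, 36 and 2606 at 0.7, 2 and 6 ppm 5 d, 66 at 2 ppm 13 w, 0 at 2 ppm 4 w, 110 and 31 for int 6 and 10 ppm, 104 for int 13 w and 4 w and 1242 for time at 0 ppm.

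With the arrays of the own times alone the counts were 1 and 0 at 0.7 and 2 ppm 5 d, 0 and 201 at 2 and 6 ppm 4 w and 7 for int 6 ppm. The RNA integrity covariate gave 0 at 2 ppm 13 w, and so did leaving out the arrays without that number (0), which also turned the share higher at 6 ppm 5 d to 53.9% from 40.0%. The beta-actin covariate gave 1 and 595 (425 higher, 170 lower) at 0.7 and 6 ppm 5 d, 3 and 8 for int 6 and 10 ppm and 847 for int 4 w and 5 d, and it reversed RT1-Ba at 6 ppm 5 d to 0.14 (-0.67 before, no longer called). With 0.7 ppm as the reference, 2 ppm gave 0 at 5 d and at 13 w. With the mean of the 0 ppm groups as the reference at 4 w, 2 ppm gave 282 (71 higher, 211 lower) and 6 ppm 1729 (571 higher, 1158 lower). Without the array of RNA integrity number 5.4, 2 ppm 4 w gave 1. The olfactory covariate gave 2 at 2 ppm 13 w, 0 and 856 at 2 and 6 ppm 4 w, 8 for int 10 ppm, 747 for int 4 w and 5 d, 17 for int 13 w and 4 w and 709 for time at 0 ppm. With the fibroblast mean added it was 0 and 931 at 2 and 6 ppm 4 w, 1 and 37 for int 6 and 10 ppm, 33 for int 13 w and 4 w and 776 for time at 0 ppm.

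Leaving out 1 array at a time gave, as lowest and highest counts, 0 and 5, 1 and 3, 558 and 1102, 1362 and 2403, and 4560 and 5525 from 0.7 to 15 ppm 5 d. At 13 w they were 0 and 1, 1 and 3, 1218 and 1475, 2896 and 3653, and 5557 and 6255, and at 4 w from 2 ppm 0 and 2, 133 and 652, 1519 and 2235, and 4600 and 5035. For int 6, 10 and 15 ppm they were 0 and 4, 1 and 7, and 1637 and 2223, for int 4 w and 5 d 349 and 577, for int 13 w and 4 w 3 and 18, and for time at 0 ppm 87 and 329. For the 223 genes called in all 9 comparisons from 6 ppm they were 101 and 269. The single animals that moved a count of 0 to 9 stand beside that count in the results above. Single animals that moved a larger count by over 1.5 times were 204 (818), 207 (815) and 300 (558) at 6 ppm 5 d, 329 (1362) at 10 ppm 5 d, 243 (304), 245 (275) and 310 (133) at 6 ppm 4 w, and 225 (180), 230 (88), 207 (87) and 208 (108) for time at 0 ppm.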

Other observations

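Genes called in the same direction at 6, 10 and 15 ppm at all 3 times numbered 162 higher and 61 lower, and 84 and 17 without 6 ppm 4 w animal 310. Over these 9 comparisons the mean log2 change was 4.44 for Sprr1b, 4.22 for Areg, 3.32 for Krt12, 2.98 for Serpinb2, 2.63 for Plaur, 2.52 for Fosl1, 2.46 for Slurp1 and 2.16 for Srxn1. Ereg, an epidermal growth factor receptor ligand, at 2.35 and Tnfrsf12a, a receptor of the tumour necrosis factor family, at 2.33 were named here after their values were seen.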
